A study of Escherichia coli with 4 samples.

How the data were processed

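Total RNA of Escherichia coli strain MG1655 was compared on 4 two-colour spotted microarrays. Per the labels, cells grew aerobically in a chemostat of 1 litre at a dilution rate of 0.1 per h, with 8 mM glycerol as the limiting source of carbon and energy, air at 1 l/min and dissolved oxygen at 40% of air saturation. A control sample was taken just before, and an exposed sample 5 min after, the nitric oxide (NO) donors NOC-5 and NOC-7 were added at 10 µM each. The series design gives 2 chemostat runs and, for each, 2 hybridisations with the dyes Cy3 and Cy5 exchanged. Arrays are named here by run and by the dye of the exposed RNA, for example run 1 Cy5.

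The deposited values, 1 per feature and array, were read as log2 ratios of exposed over control RNA. They are signed, lie between -4.35 and 6.11, and have array medians of 0.01, -0.01, 0.00 and -0.03 on the run 1 Cy5, run 1 Cy3, run 2 Cy5 and run 2 Cy3 arrays. The base of the logarithm, the background correction, the normalization, the image software and the reason for a blank value are not given in the sources used here. If the base was not 2, every fold below changes by a fixed factor on the log scale while the tests do not. No signal intensities were used here, so signal over background is unknown and the planned filter on dim features was not run. Of the 4608 features, 42.8% to 48.7% were blank per array.

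The direction of the ratio is likely exposed over control on all 4 arrays, and is not stated. It rests on 2 observations, the first for a direction shared by the arrays and the second for its overall sign. Means of the 16 print blocks correlated at -0.78 between the run 2 arrays, a permutation p of 0.00044, so that the technical component of the ratio had opposite signs in the deposited values, as it would once the swapped arrays had been turned. The genes norV and norW, known to be induced by NO, were above 0 wherever they had a value. The values were therefore used without a further change of sign, although the plan had been to turn them, and each count was repeated with the sign of both Cy3 arrays changed.

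Of the features, 4087 had 1 gene name in the platform annotation, 0 had several and 521 had none. Symbols of 197 features were updated through their gene identifiers with the gene table of assembly ASM584v2, which was used for names and for which genes neighbour each other, and 1 feature's gene was not in that table. Features of the same gene were averaged array by array, which gave 4038 genes, 49 of them with more than 1 feature. The main test took the 541 genes with a value on all 4 arrays. A looser filter, fixed beforehand, took the 2490 genes with a value on at least 1 array of each run. No columns of other samples were used.

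The chemostat run was the replicate. The arrays of a run, a technical dye swap, were averaged, so n = 2. Under the looser filter a run mean can rest on 1 array. Where both runs had only the same dye orientation, dye bias was not averaged out. For a gene on 3 arrays it was averaged out in 1 run only. Run means were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, then eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes of the filter and a threshold of 0.05. The p-values set a gene's mean against a spread between the 2 chemostat runs that limma pools over all genes of the filter. The pooled spread weighed as 69.3 degrees of freedom over the 541 genes and 6.0 over the 2490, more than a gene's own 2 runs. Gene lists were tested with limma's camera at its preset correlation of 0.01 where at least 3 members were measured, two-sided, with adjustment over the lists. Camera with an estimated correlation, fry and the rank version of camera stood beside it. The estimated correlation and its test rest on the difference between 2 runs, so that check has little power. Among genes with a value in both runs, it gave 0 of 22 lists an unadjusted p under 0.05. There were 23 lists with 475 entries, of which 473 matched a gene and 2 did not. The matched entries gave 466 different genes on the array, drawn from textbook knowledge of regulons and pathways. The lists, tests, filters, threshold, rule for named genes (apart from the number taken per list) and most alternatives were chosen before the data were examined. Centring of print blocks, the fit of 3 arrays and the repeats of counts and list tests on the looser filter were chosen after seeing the data. So was leaving the signs of the Cy3 arrays as deposited. Turning them had been the plan and was kept as an alternative.

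The rule named 3 kinds of gene. The first was the 12 largest mean rises and the 12 largest falls that passed the main test with the same sign on all 4 arrays, filled with the largest changes of the same sign on all 4 arrays where fewer passed. The second was up to 4 members of each list with the largest absolute mean change. Taking 4 for lists past the test and 2 for the others was not part of the rule fixed beforehand. The third was hmp, norV, norW, ytfE, hcp, ygbA, metE, metF, soxS, fnr, fur, nsrR and norR wherever measured. It gave 77 genes.

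The gene test was tested on simulated run means that had the spread estimated from the real ones, with 200 genes changed. With 541 genes it recovered 76.5% of 68 genes changed by 1 on the log2 scale and 100% of 66 changed by 2, and 4 of its 188 calls were false. With 2490 genes it recovered 27.9% of 68 genes changed by 1 and 100% of 66 changed by 2, and 14 of its 165 calls were false. These simulations hold no dye bias and no correlation between genes. With 200 changed genes the Benjamini-Hochberg cut-off is also looser than where few genes change, so these recovery rates do not carry over to the real data. Under the looser filter norW, at a mean of 2.85, and norV, at 3.89, both missed the threshold. Camera called an unshifted list in 0.5% of 200 simulations. A shift of 0.5 of the 9 NsrR regulon members was called in 82.5%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Cross-hybridisation between similar genes was not assessed. Alternatives were the run as a random block, arrays as independent, a gene-wise dye term, a single dye orientation, median centring and scaling, print-block centring, turned signs, each feature on its own, other thresholds, a robust prior, other list tests and leaving out each array or run.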

Results

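The data ask which transcripts of aerobically respiring Escherichia coli differ within 5 min of exposure to NO, a reactive gas that binds haem and attacks iron-sulfur clusters. Glycerol-limited steady-state cultures of strain MG1655, a K-12 laboratory strain, were sampled just before and 5 min after addition of NOC-5 and NOC-7, compounds that release NO in solution. There were 2 chemostat runs, each hybridised on 2 arrays with exchanged dyes, which gave 4 arrays and 2 independent replicates. Between 2366 and 2636 of the 4608 features had a value on an array, and 541 genes had a value on all 4. The number of arrays limits the precision, and no signal strength stands behind any value. Ratios are given as log2 of exposed over control RNA, a base and a direction that the sources used here do not state. A direction shared by the arrays is likely from the opposite print-block patterns of the swapped arrays, and exposed over control from the known NO response of norV and norW, so the sign of those 2 genes is not an independent result.

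The highest values belonged to the norVW genes, which encode the flavorubredoxin NO reductase (norV) and the reductase that supplies it with electrons (norW). The ratio of norV (b2710) was 6.11 and 5.93 on the run 2 arrays, the highest of 2314 and of 2322 genes there, and 1.76 on the run 1 Cy5 array, where it ranked 18th of 2082 genes. The ratio of norW (b2711) was 2.62 on the run 1 Cy3 array, the highest of 2151 genes, and 3.17 and 2.99 on the run 2 arrays. Neither gene had a value on all 4 arrays, so neither entered the main test. With a value in both runs, norW averaged 2.85 ± 0.32 (SD, n = 2), a 7.21-fold difference, and its limma adjusted p of 0.0508 over 2490 genes narrowly missed the threshold. The mean of norV was 3.89 ± 3.01 (SD, n = 2), and the spread between runs left it at a limma adjusted p of 0.707. Its only run 1 value came from the run 1 Cy5 array, whose ratios were unrelated to those of the other arrays, as described below. This spread can therefore not be told apart from error of that array. The run means of norW, with the Cy3 array in run 1, were 2.62 and 3.08. These values hold for the direction taken here. With the signs of both Cy3 arrays turned, the Cy3 values would be falls, and the means would be 0.92 for norV and -1.27 for norW. The regulator norR (b2709), encoded beside them, was measured on all 4 arrays at -0.78, 0.81, -0.66 and -0.56, with a mean of -0.30 ± 0.44 (SD, n = 2) and a limma adjusted p of 0.771.

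As a list, the NorR regulon rose among genes with a value in both runs, with a median of 2.85 over its 3 members (camera adjusted p = 0.0153 over 22 lists). The call came from the preset correlation. With an estimated correlation the camera adjusted p of 0.949 did not pass, but that check has little power with 2 runs. No member passed over all genes, and norV and norW, 2 of 3, passed when adjusted over the list alone. The call was also lost when arrays were scaled to the same spread (adjusted p = 0.0678) and when print blocks were centred (adjusted p = 0.0596). With the signs of both Cy3 arrays turned, the list was down and not called (adjusted p = 0.888). Without the run 1 Cy5 or the run 1 Cy3 array, the list held too few measured members to test.

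**Figure D1:**
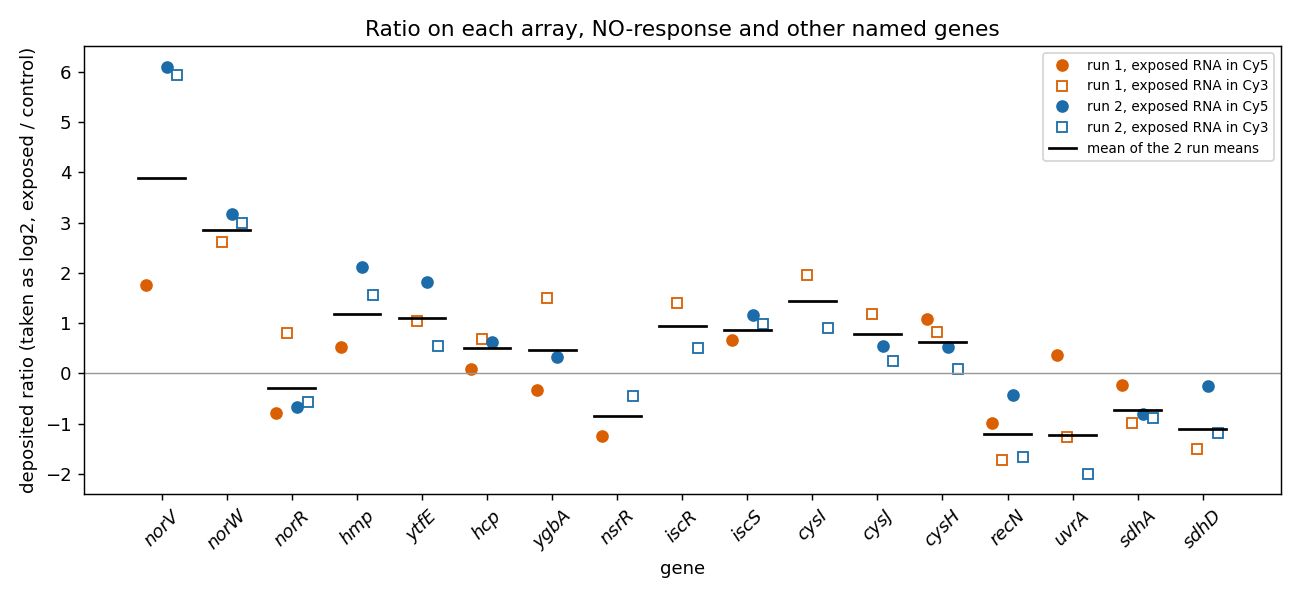
Deposited ratio (taken as log2, exposed over control) of named genes on each of the 4 arrays. Colours mark the chemostat run, filled circles the arrays with exposed RNA in Cy5, open squares those with exposed RNA in Cy3, and the line the mean of the 2 run means, without an error bar since single arrays are shown. Values of norV reach 6.11, those of norW lie between 2.62 and 3.17, and those of recN lie between -1.72 and -0.42.

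Genes of the NsrR regulon, which the NO-sensing repressor NsrR controls, had positive means for 7 of 9 measured members, and the list missed the threshold (camera adjusted p = 0.0669, and adjusted p = 0.949 with an estimated correlation). The flavohaemoglobin gene hmp, whose product oxidises NO to nitrate, averaged 1.19 ± 0.93 (SD, n = 2), with 0.53 on the run 1 Cy5 array and 2.13 and 1.57 in run 2. The iron-sulfur repair gene ytfE averaged 1.11 ± 0.10 (SD, n = 2). The hybrid cluster protein gene hcp averaged 0.50 ± 0.17, and ygbA, of unknown function, 0.46 ± 0.18. The repressor gene nsrR itself averaged -0.84 ± 0.56. No member passed over all genes, where the smallest limma adjusted p among them was 0.707, and 1 member, ytfE, passed when adjusted over the list alone. The list mean was -0.09 on the run 1 Cy5 array and 0.53, 0.66 and 0.78 on the run 1 Cy3, run 2 Cy5 and run 2 Cy3 arrays. Without the run 1 Cy5 array the list passed (adjusted p = 0.0365), and without the run 1 Cy3 array its adjusted p was 0.919.

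Of the 541 genes measured on all 4 arrays, 1 passed the main test. This was recN (b2616), an SOS gene for repair of DNA double-strand breaks, which fell by 1.20 on the log2 scale (± 0.22 SD, n = 2, SE 0.25, limma adjusted p = 0.0044), a 2.29-fold difference. Its ratios were -0.99 and -1.72 in run 1 and -0.42 and -1.66 in run 2. At an unadjusted p under 0.05 there were 45 genes, against 27.05 by chance. Under the looser filter 0 of 2490 genes passed with limma, with 158 at an unadjusted p under 0.05 against 124.5 by chance, and a robust prior also gave 0. The call of recN ended in most other fits, with limma adjusted p of 0.111 for the run as a random block, 0.402 with a dye term, 0.709 after centring of print blocks and 0.707 under the looser filter. Its mean was -1.20 in 3 of these fits and -1.14 after centring of print blocks, so the call ended while the mean barely moved. With the signs of both Cy3 arrays turned, as first planned, recN did not pass and 11 other genes did, 9 higher and 2 lower. Of the 74 named genes with a mean, 46 took the opposite sign. If the deposited values were already turned, this change makes every ratio Cy5 over Cy3. The 11 calls would then follow the dye rather than NO. They include gsiC, which had opposite signs on the Cy5 and Cy3 arrays.

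The other genes with the largest means and the same sign on all 4 arrays did not pass, with limma adjusted p between 0.135 and 0.562 for 12 positive and 11 negative genes. The positive means were led by the prophage gene ybcM (0.85 ± 0.24), the regulator gene bglJ (0.77 ± 0.39), the tyrosyl-tRNA synthetase gene tyrS (0.67 ± 0.78), ygjJ (0.67 ± 0.14), ynbB (0.66 ± 0.62), the fucose transporter gene fucP (0.66 ± 0.36) and agaR (0.66 ± 0.49; SD, n = 2 for each). They were followed by cysH at 0.63, nemR at 0.61, csgC at 0.59, yciK at 0.54 and rph at 0.52. The negative means were led by the succinate dehydrogenase gene sdhA (-0.73 ± 0.17), the fimbrial gene elfD (-0.67 ± 0.07), yjaA (-0.66 ± 0.10), yheO (-0.63 ± 0.59), yqcC (-0.62 ± 0.10) and rseC (-0.61 ± 0.22). They were followed by the phosphate transporter gene pitA at -0.57, the aldehyde dehydrogenase gene aldA at -0.56, yahL at -0.53, the fatty acid oxidation gene fadA at -0.52 and yfbO at -0.52.

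No tested list of sulfur and iron-sulfur metabolism passed. In cysteine and sulfur assimilation, 13 of 17 members were positive (camera adjusted p = 0.0669), with cysI and cysJ, which encode sulfite reductase, at 1.44 ± 0.74 and 0.79 ± 0.55 (SD, n = 2). All 6 measured members of the Isc system, which assembles iron-sulfur clusters, were positive (camera adjusted p = 0.0681), with the regulator gene iscR at 0.95 ± 0.63 and the cysteine desulfurase gene iscS at 0.87 ± 0.28. The Isc list mean was -0.43 on the run 1 Cy5 array, where 1 of 6 members was positive, and 0.64, 0.73 and 0.33 on the run 1 Cy3, run 2 Cy5 and run 2 Cy3 arrays. The mean of the sulfur list was -0.04 on the run 1 Cy5 array and 0.45, 0.24 and 0.12 on the same 3 others. Of the alternative Suf system, 2 members were measured in both runs, too few to test, with sufD at 0.53 and sufA at -0.17. The genes cysI, iscR and sufD had values on the Cy3 arrays only and sufA on the Cy5 arrays only. Dye bias was therefore not averaged out for them. No member of these lists passed over all genes or when adjusted over the list alone. Their camera adjusted p was 0.949 with an estimated correlation for the sulfur and Isc lists, a check with little power here. With the signs of both Cy3 arrays turned, the sulfur and Isc lists were both down and not called (camera adjusted p = 0.775 for each).

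No list of respiratory and energy genes passed. All 6 measured ATP synthase genes had negative means (camera adjusted p = 0.180), with atpH at -0.62 ± 0.45 and atpE at -0.56 ± 0.54 (SD, n = 2). The list mean was positive on both Cy5 arrays (0.18 and 0.09) and negative on both Cy3 arrays (-0.63 and -0.40). With the signs of both Cy3 arrays turned, the list was up and not called (camera adjusted p = 0.156). Among genes on all 4 arrays, the 5 measured members of the TCA cycle and glyoxylate shunt were negative (camera adjusted p = 0.449), with the aconitase gene acnB at -0.50 ± 0.32 and the malate synthase gene aceB at -0.32 ± 0.12. In both runs 6 of 7 were negative (camera adjusted p = 0.632). Of the aerobic dehydrogenases and oxidases 11 of 22 were negative (camera adjusted p = 0.778), with sdhD at -1.11 ± 0.56 and the cytochrome bd oxidase gene cydB at 0.97 ± 0.94. The ratio of sdhD was -0.26 on the run 2 Cy5 array, and -1.50 and -1.17 on the Cy3 arrays. On all 4 arrays 1 of 4, sdhA, passed when adjusted over that list alone and 0 over all genes. Of the anaerobic genes that FNR activates, 17 of 31 were positive (camera adjusted p = 0.673), with the fumarate reductase gene frdA at 1.03 ± 0.16 and dmsC at 0.92 ± 0.58.

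Neither the SOS list nor the list of ribosomal proteins passed. In the SOS response 9 of 13 members were negative (camera adjusted p = 0.115), with the excision repair gene uvrA at -1.22 ± 1.10 (SD, n = 2). Turned signs of both Cy3 arrays put the SOS list up, and it was not called (camera adjusted p = 0.943). In this list recN passed over all genes of the main test but not under the looser filter, and when adjusted over the list alone under both. On all 4 arrays recN was the only measured member, so adjustment over the list alone changes nothing there. Of the ribosomal protein genes 24 of 35 were negative (camera adjusted p = 0.130), with rpsK at -1.02 ± 0.66 and rpmG at -0.86 ± 0.04. The ratio of rpsK was 0.05 on the run 2 Cy5 array, and -1.48 and -1.15 on the Cy3 arrays. That of rpmG was -0.80 on the run 1 Cy5 array, and -0.87 and -0.89 on the Cy3 arrays. The ribosomal list mean was 0.11 and 0.08 on the Cy5 arrays and -0.32 and -0.28 on the Cy3 arrays. With the signs of both Cy3 arrays turned, the list was up (camera adjusted p = 0.0325).

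The remaining stress, metal and motility lists had camera adjusted p of 0.361 or more. Positive members numbered 17 of 31 for Fur-repressed iron uptake (adjusted p = 0.681), 6 of 14 for SoxRS (0.984), 4 of 10 for OxyR (0.984), 5 of 11 for heat shock (0.995), 2 of 7 for Cpx and envelope stress (0.995), 6 of 11 for RpoS general stress (0.673), 2 of 6 for acid resistance (0.884) and 6 of 13 for zinc and copper homeostasis (0.994). They numbered 21 of 32 for flagella and chemotaxis (0.361), 4 of 6 for glycerol use (0.673), 3 of 8 for methionine synthesis (0.681) and 4 of 8 for branched-chain amino acids (0.984). Median and mean had opposite signs for RpoS (0.10 and -0.12), Cpx (-0.12 and 0.01) and zinc and copper (-0.03 and 0.02), and for the aerobic dehydrogenases on all 4 arrays (0.06 and -0.08). Of Cpx, the single member on all 4 arrays, rseC, passed when adjusted over the list alone, and no other member of these lists passed either way. Among genes on all 4 arrays 0 of 8 lists passed with camera, 0 had an unadjusted p under 0.05, and fry and the rank version also called 0.

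Members of these lists with the largest means in both runs did not pass, at a limma adjusted p of 0.707 or more. Of those below, groS, metI, tolC and gadC had values on the Cy3 arrays only. The genes ahpC, poxB, fhuA, ilvI, znuB and yhiD had values on the Cy5 arrays only. Dye bias was not averaged out for either set, and a small SD between runs does not exclude it. Genes on 3 arrays, among them fecD, bolA, marA and rseA, had it averaged out in 1 run only. On the run 2 Cy5 array fecD was at -0.02, bolA at 0.08, marA at -0.35 and rseA at 0.13. In the same order, their run 1 Cy3 and run 2 Cy3 values were -1.02 and -1.80, -1.10 and -1.31, -0.87 and -1.30, and 0.68 and 1.39. The peroxidase gene ahpC averaged 0.91 ± 0.31 (SD, n = 2), the glutathione reductase gene gor -0.46 ± 0.30, the regulator gene marA -0.85 ± 0.03 and the outer-membrane channel gene tolC -0.77 ± 0.67. The iron transport genes fecD and fhuA averaged -0.97 ± 0.08 and -0.82 ± 0.78. The stress genes poxB and bolA averaged -0.93 ± 0.14 and -0.86 ± 0.34, and the chaperonin gene groS -0.60 ± 0.01. The methionine genes metK and metI averaged -0.97 ± 1.48 and -0.73 ± 0.01. The copper oxidase gene cueO averaged 0.67 ± 0.05, the anti-sigma factor gene rseA 0.72 ± 0.06 and the zinc transporter gene znuB 0.52 ± 0.73. In the glycerol list glpQ averaged 0.58 ± 0.25 and glpR -0.56 ± 0.17, and in the acid resistance list gadC averaged -0.69 ± 0.74 and yhiD 0.42 ± 0.20. In the flagellar list fliS averaged -0.78 ± 0.84 and fliH 0.65 ± 1.87. The protease gene ftsH averaged -0.63 ± 1.03, and the branched-chain genes ilvA and ilvI 0.34 ± 0.69 and 0.29 ± 0.37. Of the genes named in any case, soxS averaged -0.36 ± 0.74 and fur -0.11 ± 0.17. The methionine gene metE had 0.30 and -0.03 in run 1 and no value in run 2, metF had -0.49 on the run 1 Cy3 array only, and fnr had -0.46 and 0.14 in run 2 only.

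**Figure D2:**
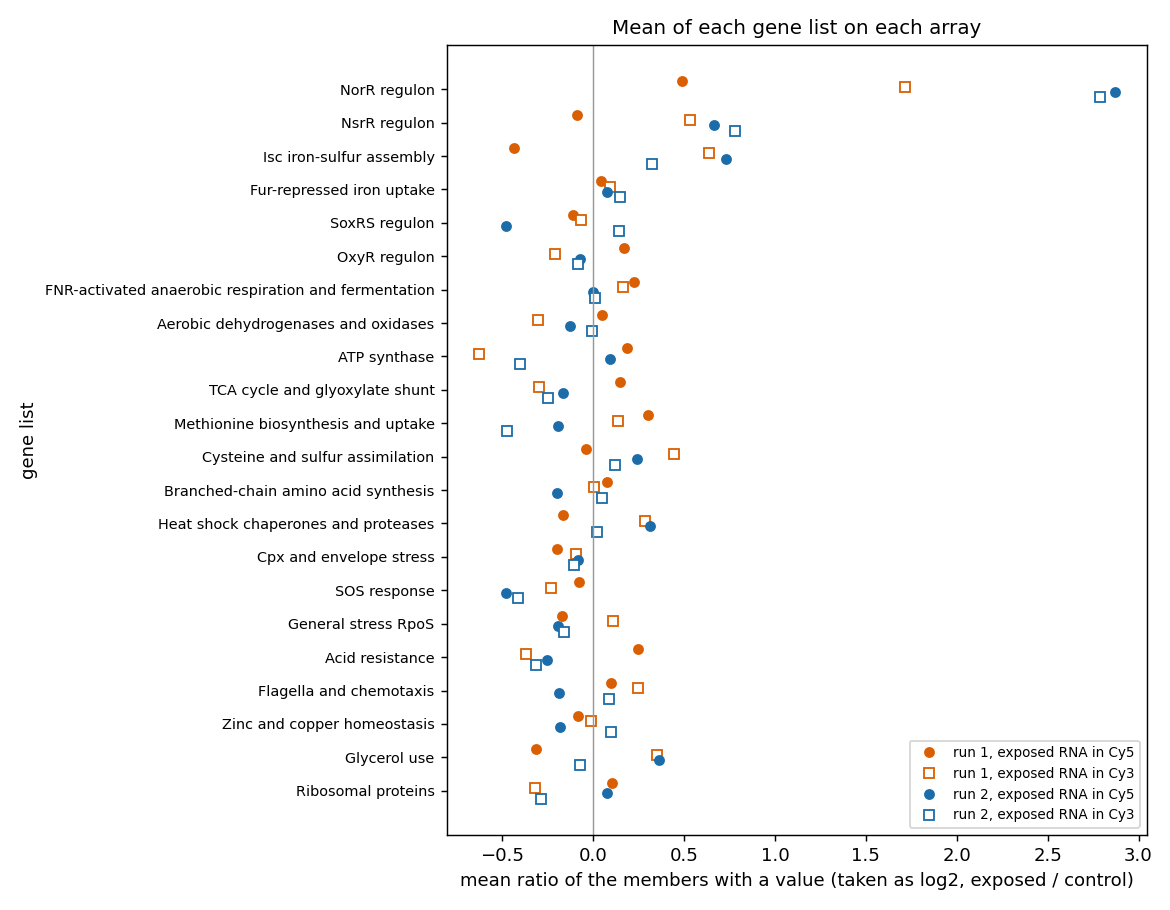
Mean ratio (taken as log2, exposed over control) of the members with a value, for each of the 22 tested lists on each of the 4 arrays. Colours mark the run, filled circles exposed RNA in Cy5 and open squares exposed RNA in Cy3, and single array means are shown without error bars. The NorR regulon lies at 2.87 and 2.79 on the run 2 arrays, over 3 members. It lies at 1.71 on the run 1 Cy3 array (norW and norR) and at 0.49 on the run 1 Cy5 array (norV and norR), so its members differ between arrays.

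Arrays agreed by dye orientation more than by chemostat run. Across features, which are not independent replicates, the 2 Cy3 arrays of different runs correlated at r = 0.399 (Spearman 0.424), while the 2 arrays of run 2, made from the same pair of RNA samples, correlated at r = -0.200 (Spearman -0.286) and had the same sign for 39.6% of 1665 shared features. The run 1 Cy5 array correlated with none of the others, at -0.010, 0.015 and -0.004. Run means of the 541 genes correlated at 0.093, and 60 of these genes, 11.1%, had the same sign on all 4 arrays, against 12.5% by chance for independent signs. With the signs of the Cy3 arrays turned, the run means correlated at 0.278. The SD of the difference between the arrays of a run was 0.925 in run 1 and 0.996 in run 2, larger than the SD of 0.606 to 0.650 of single arrays.

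**Figure D3:**
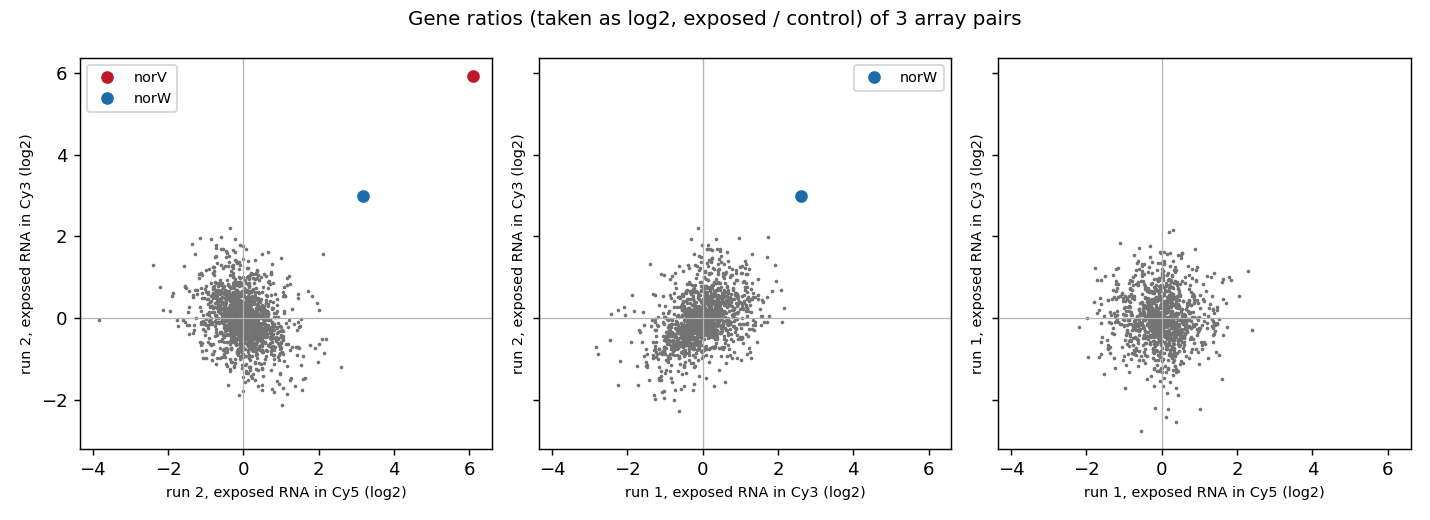
Gene ratios (taken as log2, exposed over control) of 3 array pairs, 1 point per gene, with norV and norW coloured where both arrays gave a value. From left to right the pairs are the run 2 dye swap, the 2 Cy3 arrays of different runs and the run 1 dye swap. Across features their correlations are -0.200, 0.399 and -0.010.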

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

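All tests in this part were chosen after the results were seen. In 53 sets of 4 arrays (named genes, lists and array properties), 7 had an array far from the other 3 by Dixon's gap test, where chance gives about 1 in 20, or 2.65. On the run 1 Cy3 array, tyrS was at 2.16, norR at 0.81 and the RpoS list mean at 0.11. On the run 1 Cy5 array, acnB was at 0.23, yfbO at -1.62 and the Cpx list mean at -0.20. The SD of the run 2 Cy5 array was 0.606. Features without a gene name, 323 in both runs and 53 on all 4 arrays, gave 0 calls with limma, with 21 and 5 at an unadjusted p under 0.05.

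The run 1 Cy5 array was unrelated to the others feature by feature. A detachment of its values from their features over the whole array is argued against by its print-block means, which correlated at -0.832 with those of the run 2 Cy3 array (permutation p = 7e-05). A different response in chemostat run 1 would leave the Cy5 pair of arrays from different runs as correlated as the Cy3 pair, since both pairs share dye bias and response alike. Over 587 features on all 4 arrays the Cy3 pair was higher by 0.350 (95% interval 0.225 to 0.476, from 10000 resamplings of print blocks), which argues against it as the whole cause. Noise, or a mix-up of features within print blocks, stays open. After centring of blocks, the array's largest correlation with another was 0.026, against absolute values of 0.144 to 0.382 between the others. Its blank features were unrelated to those of the others too. Being blank correlated at 0.011, -0.017 and 0.012 with them, and at 0.150 to 0.183 between the others. Why values are blank is unknown, so this does not separate noise from a mix-up. The main test used only genes with a value on the run 1 Cy5 array. The ratio of norV there, 18th of 2082 genes, may point to weak signal under noise, and was a single gene picked for its response.

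Of the 4 pairs of arrays of opposite dye orientation, the run 2 arrays (r = -0.200) and the run 1 Cy3 and run 2 Cy5 arrays (r = -0.201) correlated below 0, and the pairs with run 1 Cy5 were near 0. Deposition of the swapped arrays without turning the ratio is argued against by the block means of the run 2 arrays, which correlated at -0.780 (permutation p = 0.00044), where unturned values would give a positive correlation. Dye bias left in turned values stays open, since features without a gene name showed it too (r = -0.308 between the run 2 arrays). No biological explanation was tested, because both arrays of a run carry the same RNA.

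Dye bias was then set against 4 list shifts, since it predicts opposite signs on the Cy5 and Cy3 arrays of a run. For ribosomal proteins the run 2 means were 0.079 on Cy5 and -0.28 on Cy3, and for ATP synthase 0.092 and -0.40, with the same order of signs in run 1. The members with a value differed between arrays. Over the 33 ribosomal members on both run 2 arrays the means were 0.039 and -0.21, with 13 of the same sign on both. Over 3 ATP synthase members they were 0.019 and -0.28, with 1 of the same sign. Dye bias stays open for both lists, as does an effect of NO. Averaged over dyes, their members kept means of -0.11 (exact signed-rank test over 38 members, p = 0.027) and -0.21 (the same test over 6 members, p = 0.031). That test treats members as independent, which genes measured on the same arrays are not, and 0.031 is the smallest p that 6 members can give. Only 16 of 38 and 1 of 6 members had the same sign on both dyes. With a dye term neither list stood out from other genes (camera adjusted p = 0.333 and 0.391).

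Fits with a dye term count arrays rather than runs as replicates, and their list tests use camera at its preset correlation. Because they rest on that preset, these list calls were not taken as enough. Without a dye term, camera with an estimated correlation gave an adjusted p of 0.949 for both NorR and NsrR. With 2 runs that check has little power, so it decides nothing here. For NorR the run 2 means were 2.87 and 2.79, and the dye term on 4 arrays kept the list up (adjusted p = 3.92e-12, 3 members). As a single gene, norW passed with that term (limma adjusted p = 0.0125), and norV was at 6.11 and 5.93 on the run 2 arrays. The mean of the 3 members averaged over dyes was 2.54 ± 1.53 (SE over members, exact signed-rank p = 0.5, too few members to pass), with norR below 0. The values of norV and norW argue against dye bias as the whole cause for NorR, given turned values, which the block means argue for without norV and norW. Of NorR only the match of signs counts here, because norV and norW fixed the overall sign. For NsrR the run 2 means were 0.66 and 0.78, and 1.08 and 1.30 over the 3 members on both arrays, of which 2 had the same sign on both. The list was up with the dye term on 4 arrays (adjusted p = 0.0156, 8 members) and on 3 arrays (adjusted p = 0.0196). Of 8 members with values on both dyes, 6 had the same sign on both. They include hmp, ytfE and hcp, above 0 on both, and nsrR, below 0 on both. However, its run 1 means were -0.09 and 0.53, no single member passed with the term, and the mean of these 8 members averaged over dyes was 0.44 ± 0.27 (SE over members, exact signed-rank p = 0.195), so dye bias cannot be told apart from other causes there. A response to NO stays a candidate explanation for both lists, as a hypothesis from 2 runs.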

How the results depend on the processing

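Print-block centring and the 3-array fit were chosen after the data were seen, as were the repeats of counts and list tests on genes with a value in both runs. Turned signs had been the plan, and leaving the signs as deposited was chosen after the data were seen. In each sentence the cause was not tested unless a smaller set of genes or arrays is named.

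The main count of 1 gene became 0 with the run as a random block, with arrays as independent, with a dye term, with Cy3 arrays alone, with centred print blocks, with a dye term on 3 arrays, with a value needed in both runs only and with at least 2-fold on every array. It became 11 with turned signs, and 0 to 2 when an array was left out (2, recN and mppA, without run 2 Cy5). With Cy5 arrays alone it was 1, but that gene was gsiC (both genes named after their values were seen). Among genes with a value in both runs, the count of 0 became 1 (norW) with the random block, independent arrays, the dye term, median centring, features tested singly or a threshold of 0.1. It became 3 with Cy5 arrays alone, 36 at a mean of 2-fold with the same sign on every measured array, 6 at 2-fold on each measured array, and 0 to 2 when an array was left out. These 2 fold settings have no test.

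The count of 0 lists became 1 with a value needed in both runs (more genes enter) and 0 to 1 when an array was left out (1, SOS, lower, without run 2 Cy5). Among genes in both runs, the count of 1 list became 4 with the random block (NorR, NsrR and Isc higher, SOS lower) or independent arrays (NorR, NsrR, Isc and cysteine, all higher), 2 with the dye term (NorR and NsrR, higher) or Cy3 arrays alone (flagella higher, ribosomal proteins lower, NorR too small to test), and 0 with Cy5 arrays alone (NorR too small to test), scaled arrays, an estimated correlation, fry or ranks. It was 0 to 2 when an array was left out: 0 without run 1 Cy3, and 2 without run 1 Cy5 (NsrR higher, ribosomal proteins lower), run 2 Cy5 (NorR and flagella, higher) or run 2 Cy3 (NorR and NsrR, higher). It stayed at 1 with other lists: Isc for centred blocks, NsrR for the 3-array fit and ribosomal proteins, higher, for turned signs. With camera at its preset correlation, over the 13 settings of arrays, model or centring that could test NsrR, turned signs aside, its direction was the same, with adjusted p from 0.0024 to 0.919. With turned signs both NsrR (adjusted p = 0.970) and NorR (0.888) were down. Over 8 settings for NorR it was the same too, with the highest at 0.0678, and for ribosomal proteins it was the same in 11 of 13. An estimated correlation, ranks and fry gave adjusted p of 0.949, 0.169 and 0.611 for NsrR, and 0.949, 0.445 and 0.324 for NorR.

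The correlation of run means, 0.093, became 0.349 with Cy3 arrays alone and 0.278 with turned signs, and ranged from -0.17 (without run 2 Cy3) to 0.27 when an array was left out. Of single genes, fliH turned to -0.082 with the random block and norR to 0.12 with Cy3 arrays alone. Leaving out an array or a run gave ranges across 0 for fliH (-0.67 to 1.97), ilvA (-0.15 to 0.82), fur (-0.23 to 0.0089), norR (-0.69 to 0.10), soxS (-0.89 to 0.16), ftsH (-1.36 to 0.10) and metK (-2.02 to 0.076). Turned signs, left out of the next counts, changed the sign of 46 of 74 named genes. Under the remaining settings the other comparisons of named genes kept their direction and, where tested, their side of the threshold in 938 cases, lost the call in 11 (all recN) and gained it in 9 (norV and norW).

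Leaving out a whole run leaves 1 replicate, so values were taken with no test. The filter on low signal was not run. No paired analysis was possible because each ratio already sets the exposed against the control sample of its own run. Without intensities, what signal over background limits is unknown.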

Other observations

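The test in this part was chosen after the result was seen. Besides norV and norW, 4 genes outside the naming rule had ratios of at least 2-fold with the same sign on each array that measured them, in both runs, and were picked after their values were seen. The glutamate and aspartate transporter gene gltK had -1.03 and -1.95, the macrolide exporter gene macB 1.78 and 1.21, the prophage gene pinR 1.15 and 1.32, and the regulator gene yeiL 1.47 and 1.32. Each was measured on 1 array per run, and each had a limma adjusted p of 0.707. Dye-linked ratios were seen for gsiC, a glutathione transporter gene, at 1.23 and 2.19 on the Cy5 arrays and -0.98 and -0.52 on the Cy3 arrays. A dye term called 0 of 541 genes with limma, with 70 at an unadjusted p under 0.05.

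Neighbouring genes often share a transcript, so real changes may appear as similar ratios of adjacent genes. The pairs below were taken without regard to strand, overlapping genes included, so near pairs may hold genes that share no transcript. In the dye-averaged run 2 values, after centring of blocks, genes under 30 bases apart correlated at 0.515 over 179 pairs, against -0.069 over 134 pairs more than 150 bases apart. Without the norV and norW pair the correlation was 0.051 (permutation p = 0.504, 100000 permutations), so in these values the relation rests on that pair. On single arrays, near pairs without these genes and far pairs correlated, in that order, at 0.140 and 0.145 on run 2 Cy3, 0.099 and -0.006 on run 2 Cy5, 0.122 and 0.070 on run 1 Cy3, and 0.015 and 0.049 on run 1 Cy5. Permutation p of the near pairs was, in the same order, 0.00262, 0.0345, 0.0171 and 0.760, and 0.0157, 0.069, 0.051 and 0.760 after adjustment over 6 sets of values, so near pairs other than norV and norW were correlated on run 2 Cy3. Far pairs there were correlated as much, and dye bias was not removed on single arrays. The differences between near and far pairs were not tested, so shared changes of other neighbours stay open. Of all 1405 pairs of genes on the array under 30 bases apart, 3 lay in the same print block.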
